A study of Mus musculus with 24 samples.

How the data were processed

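RNA was sequenced from the mouse mastocytoma line P815 in 8 groups of 3 libraries, 24 in all. Cells carried a negative control vector (NC), carried a vector with an Esr1-specific short hairpin RNA (SH), or were treated with the antiestrogens ICI-182780 (fulvestrant; ICI) or tamoxifen (Tamo). Each arm was sampled without and with β-estradiol (E2). The labels give 24 h of treatment for every group except NC and SH without E2, for which they state no time. Doses are not in the labels, no vehicle-only or untransfected group is labelled, and the inhibitor arms are not labelled as carrying a vector, so a difference between an inhibitor arm and NC cannot be assigned to the drug alone. The labels do not say whether the 3 libraries of a group are separate cultures. The p-values therefore measure the spread between these samples, which may be technical. Per the labels, cells grew in RPMI-1640 with 10% fetal bovine serum, RNA was extracted with TRIzol, and libraries were made from total RNA by standard Illumina methods. The strand protocol is not stated, so overlapping and antisense genes cannot be told apart.

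Reads were trimmed with cutadapt and aligned with HISAT2 to GRCm38 according to the submitters' processing notes, which give no versions. The quantifier and the gene annotation are not given in the sources used here. The authors deposited a single table of 55385 genes with 55253 symbols. It holds FPKM values and, per the file headers, counts for each of the 24 libraries, with 0 columns of other samples. The deposited FPKM values carry a small placeholder for no signal: 99.998% of the 866073 placeholder cells have a count of 0. The deposited counts are given per gene, per the file headers, and are not normalized. They are whole numbers, but were taken as estimated counts (expected counts) made by the authors, since low values pile up at a few sizes. A count of 4 makes up 16.2% of all values from 1 to 40, a count of 8 another 9.11% and a count of 12 another 5.13%. A read pair thus appears to be worth up to about 4 of them, and an alternative with the counts divided by 4 and rounded was added. Totals ran from 42.1 to 68.8 M estimated counts per library (median 54.2), with 18637 to 20335 genes detected. Mitochondrially encoded genes took 4.76% to 5.95% of each library (median 5.17%) and the top 10 genes 5.38% to 6.50%.

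Genes entered the tests with 1 FPKM or more in at least 3 of the 24 libraries, which left 12183 genes (9929 protein-coding) of 28735 features with a count. Counts were scaled by TMM (factors 0.969 to 1.05) and fitted in edgeR 4.0.16 by quasi-likelihood with 1 coefficient per group over all libraries and no replicate block. The plan named limma-trend on log2(FPKM + 1) for a table without raw counts and edgeR for one with them; the estimated counts were treated by the latter, and limma is given as an alternative. Tests were two-sided and adjusted by Benjamini-Hochberg over all genes tested, and a gene passed at an adjusted p under 0.05. The common dispersion was 0.0712 and the median standard error (SE) of a log2 fold change between groups of 3 was 0.21. SE is the absolute log2 fold change over the square root of the F statistic. Errors given with FPKM are SD over the 3 libraries of a group. Where a group had almost no counts, a bound on the fold is given with a floor of 12 counts per library, about 3 read pairs. With 3 libraries against 3, the smallest exact permutation p is 0.1 and 10% of unchanged genes do not overlap between the groups by chance.

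Before the data were examined, 11 contrasts were fixed: E2 in each of the 4 arms, SH, ICI and Tamo against NC without E2, ICI against Tamo, and the difference of the E2 effect in SH, ICI and Tamo from that in NC. The Esr1 level, correlations between contrasts, 34 gene lists, the rule for named genes and the alternatives were fixed with them. The mean E2 effect over the 4 arms, the SH, ICI and Tamo effects in the presence of E2, the fits on replicates 2 and 3 alone, the count without chromosome 19 and the counts divided by 4 were added after the data were seen. Genes named per contrast had a symbol that is not a predicted or clone name and a protein-coding biotype. They were the 10 (E2 in NC and SH against NC) or 5 (other contrasts) rising and as many falling genes with the largest log2 fold change among those that passed and whose groups did not overlap. Contrasts of E2 effects had no overlap condition. Where none passed, the 5 genes with the smallest p are given as values. Up to 4 members of each list that passed, and always Esr1, Esr2, Gper1, Greb1, Pgr, Kit, Fcer1a, Cpa3 and Hmgcs1, complete the rule, with a further gene that is not reported here; other genes are said to have been chosen after their values were seen.

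The lists covered estrogen receptors and coregulators, estrogen response genes, mast cell genes, cytokines, interferon response, antigen presentation and checkpoint genes, p53 targets, apoptosis, S phase, mitosis, cholesterol and fatty acid synthesis, LXR targets, lysosome, unfolded protein response, amino acid stress, heat shock, NRF2 and AhR targets, hypoxia and glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, MAPK feedback and immediate early genes, NF-kB targets, actin, histones and markers of 6 other cell types. Of these, 28 had at least 5 tested members. They were tested with camera of limma 3.58.1 (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists of a contrast), with camera on an estimated correlation, and with fry. AhR targets (2 tested members), T and NK cells (2), B cells (1), macrophages and neutrophils (3), fibroblasts and endothelium (2) and epithelium (0) had too few tested members and are given as levels or not further analysed. Interferon, antigen presentation, NF-kB, cytokine and other lists share members.

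Replicate numbers were checked for pairing. Deviations from the group means correlated between libraries of the same number (median 0.232 over 84 pairs, 77 of them over 0.1) and not between different numbers (median -0.141), and 23 of 24 libraries were closest to their own number. In each of the 8 planned contrasts of 2 groups, all 3 pairs were over 0.1 (lowest 0.145). The numbers were therefore taken to pair the libraries there, from the data and not from the labels, and a fit with the replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times. The same held for Tamo_E2 against NC_E2 (lowest 0.123). In SH_E2 against NC_E2 and ICI_E2 against NC_E2 the lowest pair was under 0.1 (0.0967 and 0.0949). In the blocked fit 4611 of 12183 genes differed between replicates 1 and 2, 5190 between 1 and 3 and 2363 between 2 and 3.

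Alternatives were no filter, a filter of mean FPKM 5, median-of-ratios scaling, robust dispersion, only the groups of a contrast, the replicate block, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn. Correlations between contrasts were taken over the 12183 genes tested, beside 20 simulations from the fitted dispersions with no effect. Genes are not independent replicates, so no p is given. The simulations drew each gene independently apart from the replicate-number effects, so their ranges may be too narrow for real libraries. On simulated data with changes planted in the E2 contrast in NC, edgeR found 13.4% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 71.2% of those changed 3-fold. For the mean over the 4 arms these shares were 64.2%, 89.6% and 97.0%, and for the difference of the E2 effect between SH and NC 2.99%, 19.4% and 56.1%. With the replicate block they were 32.8%, 68.7% and 78.8% for E2 in NC (9 false calls against 0), 71.6%, 92.5% and 97.0% over the 4 arms (6 against 3), and 17.9%, 50.7% and 77.3% for the difference (5 against 1). R 4.3.3 was used with the package data.table (version 1.17.8), and matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 drew the figures. Reads themselves were not used here.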

Results

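The transcriptome of P815 mastocytoma cells was compared with and without β-estradiol (E2) in 4 arms: vector control (NC), Esr1 short hairpin RNA (SH), ICI-182780 (ICI) and tamoxifen (Tamo). Each of the 8 groups had 3 libraries of 42.1 to 68.8 M estimated counts, and 12183 genes were tested. The largest component of variation, 21.6%, separated the SH libraries from the rest, and the next, 13.6%, separated replicate 1 from replicates 2 and 3. Unless another test is named, adjusted p values are from edgeR quasi-likelihood with Benjamini-Hochberg adjustment, errors of log2 fold changes are SE, errors of FPKM are SD, and n = 3 per group.

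How strongly the cells express the receptors of E2 was examined first. Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614, GRCm38), the gene of estrogen receptor alpha, was low in every library, at 0.161 to 0.520 FPKM and 156 to 433 estimated counts. Its group means were 0.342 ± 0.135 FPKM in NC, 0.314 ± 0.0781 in NC_E2, 0.278 ± 0.0620 in SH and 0.215 ± 0.0369 in SH_E2. In the inhibitor arms they were 0.356 ± 0.153 in ICI, 0.296 ± 0.125 in ICI_E2, 0.329 ± 0.0981 in Tamo and 0.334 ± 0.0572 in Tamo_E2. Over both E2 conditions the SH libraries held 26.4% less Esr1 than NC (log2 difference -0.44, lower in 5 of 6 pairs), which did not pass the stratified exact permutation test (two-sided p = 0.085, smallest reachable 0.005). An exact sign-flip test over the pairs gave p = 0.125. Without NC replicate 3 the difference over both conditions was -0.63 and passed (stratified exact permutation p = 0.02). Leaving that library out breaks up the pair that went the other way (0.187 FPKM in NC replicate 3, 0.260 in SH replicate 3). In the libraries without E2 alone it was -0.29 (exact permutation p = 0.5, smallest reachable 0.1). The edgeR estimate over both conditions was -0.48 ± 0.25 (unadjusted p = 0.0684), and -0.42 ± 0.18 with the replicate block (unadjusted p = 0.0302). The other receptors were near absent: Esr2, estrogen receptor beta, had 0 to 8 estimated counts, the membrane receptor gene Gper1 0 to 8, and Pgr, a classical estrogen target, 0 to 4. These levels are of messenger RNA, and protein was not analysed here.

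**Figure D1:**
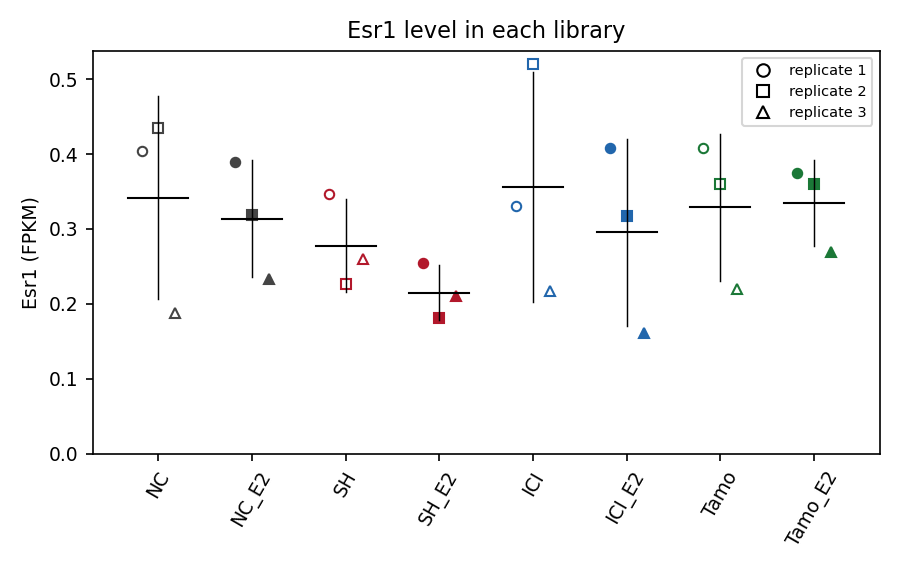
Esr1 in FPKM (vertical axis, from 0) in the 8 groups; each point is a library (shape gives the replicate number, open without and filled with E2), and lines give the mean ± 1 SD, n = 3. Group means run from 0.215 FPKM in SH_E2 to 0.356 in ICI. All groups overlap except SH_E2 (at most 0.254 FPKM) and Tamo_E2 (at least 0.269).

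Whether E2 changes the transcriptome of vector control cells was the central comparison. No gene passed. The smallest p belonged to Ccdc71 (ENSMUSG00000049305), at 3.83 ± 0.510 FPKM in NC and 8.26 ± 2.90 in NC_E2 (log2 fold change 1.11 ± 0.19, edgeR adjusted p = 0.150). Next came Mmgt2, a magnesium transporter gene, at 0.301 ± 0.103 and 2.61 ± 0.844 FPKM (3.08 ± 0.57, edgeR adjusted p = 0.195), and Akap12, a kinase anchoring protein gene (-0.77 ± 0.17, edgeR adjusted p = 0.786). For Ccdc71 and Mmgt2, NC was low beside the other groups without E2. The SH, ICI and Tamo libraries without E2 already held 8.782 to 11.17 FPKM of Ccdc71 and 1.197 to 3.474 of Mmgt2. Of the libraries with E2, ICI_E2 replicate 3 was as low as NC for Mmgt2 (0.2942 FPKM). For these genes an effect of E2 in NC therefore cannot be told apart from a low NC group. Galnt10, a glycosyltransferase gene, had 0.59 ± 0.14 and Pagr1a 2.01 ± 0.51. Greb1, an estrogen receptor target in breast cells, stood at 3.83 ± 1.15 FPKM in NC and 2.91 ± 0.459 in NC_E2 (-0.40 ± 0.30, edgeR adjusted p = 0.9998). Of 19 tested estrogen response genes 0 passed over all genes and 0 when adjusted over the list alone (median log2 fold change -0.05, camera adjusted p = 0.704).

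For E2 in NC edgeR called 0 of 12183 genes, with 244 at an unadjusted p under 0.05. It called 0 with the replicate block (529 at an unadjusted p under 0.05), limma called 0 with either pseudocount, DESeq2 called 4 and edgeR on the 6 libraries alone called 3. Leaving out NC replicate 2 or NC_E2 replicate 2 gave 1 gene, in the latter case Ccdc71 (1.36, edgeR adjusted p = 0.000192). NC_E2 replicate 2 was the NC_E2 library with the lowest Ccdc71 level (5.081 FPKM). The 95% interval of 80.5% of genes lay within a 2-fold change either way. Of the gene lists, 3 had small shifts. Cytosolic ribosomal protein genes (median log2 fold change 0.12, camera adjusted p = 7.35e-07) and oxidative phosphorylation genes (0.09, camera adjusted p = 0.000115) were shifted up. Mitochondrially encoded genes were shifted down (-0.11, camera adjusted p = 0.00239), and their share of the library was 5.34 ± 0.134% in NC and 4.98 ± 0.206% in NC_E2. With an estimated correlation all 3 had an adjusted p = 0.959, and 0 members of any list passed, over all genes or over the list alone.

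The same question was put to the other arms, where the receptor was targeted. In SH cells Zfp260, a zinc finger gene, had 2.69 ± 0.43 with E2 (0.538 to 3.47 ± 2.22 FPKM, edgeR adjusted p = 0.0596), Arl16 1.10, Tex264 0.40 and Nlrp3 2.28; Aspg, near the detection floor in both SH groups, also had a small p. Without SH_E2 replicate 1, Zfp260 passed (3.15, edgeR adjusted p = 2.74e-05). It stood at 3.396 to 6.015 FPKM in all libraries outside the SH arm, with or without E2. Only the SH libraries (0.291 to 0.667 FPKM) and SH_E2 replicate 1 (0.937), the library left out, were low. In ICI cells Nlrp3, the sensor of an inflammasome, had 3.91 ± 0.65 (edgeR adjusted p = 0.0973), and it passed with the replicate block (3.77, edgeR adjusted p = 0.00658) and without ICI_E2 replicate 3 (4.29, edgeR adjusted p = 0.0297). Eif1a, a translation initiation factor gene, had -1.37 in ICI cells (53.4 to 20.4 FPKM), Galnt10 0.68, Epb41l4b 0.53 and Por 0.30. Single libraries of other groups were as low for Eif1a, with 19.69 FPKM in NC replicate 1 and 17.45 in SH_E2 replicate 3. The other libraries of those groups had 48.37 to 53.52, so the level also switched without regard to E2 or ICI. In Tamo cells Esco1, a cohesin acetyltransferase gene, had 0.62 ± 0.10 (7.45 to 11.4 FPKM, edgeR adjusted p = 0.0763), Esf1 0.39 and Caap1 0.48. With the replicate block, Esco1 (0.62, edgeR adjusted p = 0.0251), Nlrp3 (2.92, edgeR adjusted p = 0.0371) and Prr14 (-0.56, edgeR adjusted p = 0.0371) passed in Tamo cells, against edgeR adjusted p = 0.908 for Nlrp3 and Prr14 without it.

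Without the block edgeR called 0 genes with E2 in each of these arms: SH with 163 at an unadjusted p under 0.05, ICI with 224 and Tamo with 434. With the replicate block edgeR called 0 in SH, 1 in ICI and 3 in Tamo, with 291, 483 and 1073 at an unadjusted p under 0.05. DESeq2 called 2, 10 and 6, edgeR on the 6 libraries alone 3, 3 and 0, and limma 0 in each. Leaving out Tamo replicate 3 gave 1 gene in Tamo. Among the lists, ribosomal protein genes were shifted up in SH (camera adjusted p = 0.0231; adjusted p = 0.994 with an estimated correlation). In ICI, ribosomal protein genes (camera adjusted p = 7.44e-08) and oxidative phosphorylation genes (camera adjusted p = 3.7e-06) were shifted up (adjusted p = 0.980 with an estimated correlation for both). In Tamo, mitochondrially encoded genes were shifted up (camera adjusted p = 0.0180; adjusted p = 0.990 with an estimated correlation). Of these lists 0 members passed in any arm.

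Whether the E2 effect itself differed from that in NC was tested for each arm, and 0 genes passed. For SH the smallest p belonged to Zfp260 (2.77), Mmgt2 (-3.10), Ccdc71 (-1.05), Akap12 (0.87) and Nfe2 (-1.98). For ICI they were Mmgt2 (-3.42), Furin (-1.81), Ccdc71 (-1.06), Eif1a (-1.72) and Sacm1l (0.84), and for Tamo Esco1 (0.77, edgeR adjusted p = 0.323), Ccdc71 (-1.38), Tmed5 (0.66), Sema3d (0.65) and Tmem33 (0.64). edgeR gave 139, 132 and 495 genes at an unadjusted p under 0.05 for SH, ICI and Tamo. It called 0 with the replicate block (239, 278 and 1168 at an unadjusted p under 0.05) and limma called 0 for each, while DESeq2 called 1, 4 and 16 and edgeR on the libraries of the contrast alone 0, 0 and 1. Without NC_E2 replicate 2, Ccdc71 passed for SH (-1.31, edgeR adjusted p = 0.0265), ICI (-1.31, edgeR adjusted p = 0.0264) and Tamo (-1.63, edgeR adjusted p = 0.00119). The library left out had 5.081 FPKM, against 8.956 and 10.75 in the other NC_E2 libraries. These differences share the NC libraries, which were low (3.332 to 4.351 FPKM). In SH, ICI and Tamo the gene already stood at 8.782 to 11.17 FPKM without E2. Mmgt2 was likewise low in NC (0.1964 to 0.4023 FPKM) and stood at 1.197 to 3.474 in SH, ICI and Tamo without E2. Zfp260 passed for SH without SH_E2 replicate 1 (3.23, edgeR adjusted p = 0.00127), the SH_E2 library in which it was low (0.937 FPKM). For Tamo, 1 gene passed without NC replicate 2 or NC_E2 replicate 3.

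Across the 12183 genes, E2 effects in NC correlated with those in SH at r = 0.157 (Spearman 0.225; r = 0.644 among genes with a mean FPKM of 5 or more), in ICI at 0.0393 (0.268) and in Tamo at -0.0406 (-0.143). Simulations with no effect ran from -0.0790 to 0.0975, from -0.0789 to 0.0668 and from -0.0787 to 0.128. They covered all 12183 genes, so the value of 0.644 has no simulated range to be set against. Between the other arms the values were -0.0890 for SH with ICI (Spearman 0.204; -0.0821 to 0.0800 in simulations), -0.114 for SH with Tamo (-0.0474; -0.117 to 0.0920) and 0.111 for ICI with Tamo (0.0130; -0.0830 to 0.0576). Thus 3 of the 6 values of Pearson r lay outside their simulated range, 2 above and 1 below. The tally depends on the measure. SH with ICI, the value below, had a positive Spearman value (0.204, simulated mean -0.00276). NC with ICI, inside its range, had the highest Spearman value of the 6 (0.268, simulated mean -0.00192). The 6 pairs are among 19 correlations computed across genes, and genes are not independent replicates.

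To gain precision, the E2 effect was averaged over the 4 arms, a contrast chosen after the data were seen. Nlrp3 (ENSMUSG00000032691, chromosome 11, 59541568 to 59566956) rose most among protein-coding genes, by 2.72 ± 0.31 on the log2 scale (edgeR adjusted p = 0.00037), and was higher with E2 in 12 of 12 same-numbered pairs. It went from 1.56 ± 0.277 to 5.98 ± 2.38 FPKM in NC, 0.584 ± 0.129 to 2.85 ± 1.71 in SH, 0.369 ± 0.155 to 5.59 ± 4.43 in ICI and 0.727 ± 0.638 to 4.95 ± 1.03 in Tamo. Galnt10 (0.53 ± 0.07, edgeR adjusted p = 0.00293) and the ubiquitin ligase subunit gene Rmnd5b (ENSMUSG00000001054; 0.42 ± 0.07, edgeR adjusted p = 0.0411) rose in 12 of 12 pairs. So did Epb41l4b, of the band 4.1 family (0.31 ± 0.06, edgeR adjusted p = 0.0411). Por, the electron donor of microsomal cytochromes P450, rose by 0.22 ± 0.04 (84.5 ± 4.15 to 102 ± 3.43 FPKM in NC, edgeR adjusted p = 0.0411), higher in 11 of 12 pairs.

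The contrast over the 4 arms called 7 genes in edgeR, 6 rising and 1 falling, with 295 at an unadjusted p under 0.05. The other 2, named after their values were seen because their symbols fall outside the rule, were 5031439G07Rik (0.68 ± 0.12, edgeR adjusted p = 0.0411) and Gm49378 (-2.76 ± 0.44, edgeR adjusted p = 0.021). With the replicate block edgeR called 14 (662 at an unadjusted p under 0.05), among them all 7; limma called 2 with either pseudocount and DESeq2 12. Nlrp3 and Galnt10 kept their call without any 1 library. The total was 2 without ICI_E2 replicate 1 or 2, NC_E2 replicate 1 or 3, SH_E2 replicate 2, Tamo replicate 2 or Tamo_E2 replicate 1. It was 3 without ICI replicate 2, NC replicate 1 or 2, SH replicate 2 or 3, SH_E2 replicate 1 or 3 or Tamo_E2 replicate 2, and 4 without ICI replicate 1, NC replicate 3 or SH replicate 1. Replicates 2 and 3 alone gave 0. Ribosomal protein genes (camera adjusted p = 3.47e-07) and oxidative phosphorylation genes (camera adjusted p = 0.000241) were shifted up, with 0 members passing and an adjusted p = 0.936 with an estimated correlation for both.

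**Figure D2:**
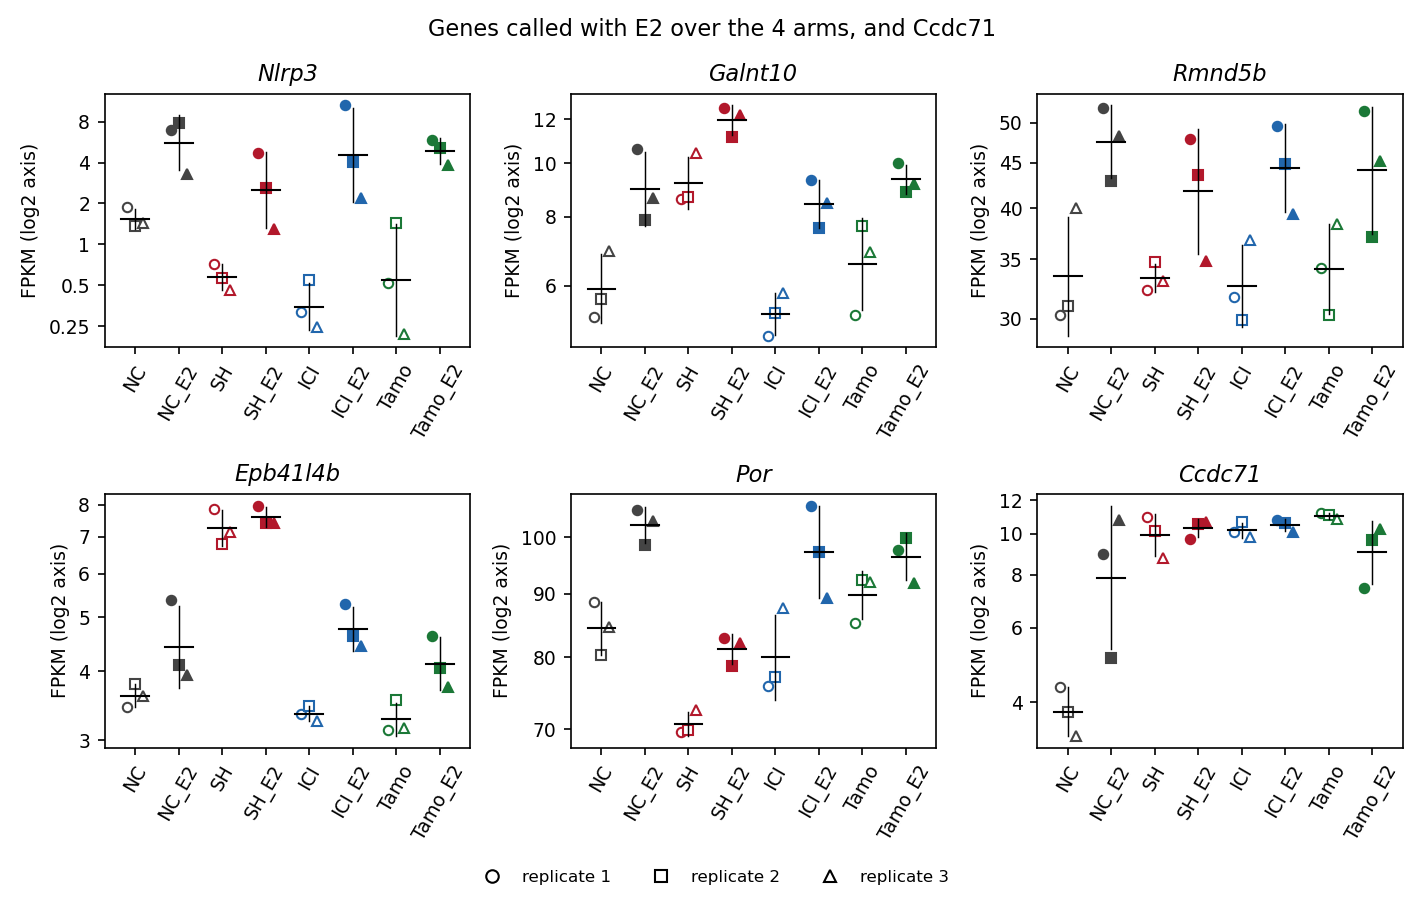
FPKM (log2 axis) of Nlrp3, Galnt10, Rmnd5b, Epb41l4b, Por and Ccdc71 in the 8 groups; each point is a library (shape gives the replicate number, open without and filled with E2), and lines give the geometric mean ± 1 SD, n = 3. Nlrp3 is higher with E2 in all 4 arms, and Ccdc71 is lowest in NC (arithmetic mean 3.83 FPKM).

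What distinguishes SH cells from vector controls was asked next, without E2. Among effector and protease genes, Gzmb, the cytotoxic protease granzyme B (ENSMUSG00000015437), fell from 66.2 ± 1.01 to 4.48 ± 2.39 FPKM (-3.94 ± 0.29, edgeR adjusted p = 4.79e-08). Gzmc, granzyme C, was at least 12.5-fold lower (edgeR adjusted p = 0.00291). That bound is on the mean of NC libraries that ran from 0.701 to 4.37 FPKM, so it rests on the higher ones. The carboxypeptidase gene Cpvl fell from 107 ± 12.3 to 10.4 ± 0.785 FPKM (-3.42 ± 0.16, edgeR adjusted p = 1.52e-10). The mast cell receptor gene Mrgprb1 fell by 4.83 ± 0.27 (edgeR adjusted p = 9.55e-10). Cpa3, the mast cell carboxypeptidase A3, rose from 219 ± 61.1 to 517 ± 47.2 FPKM (1.18 ± 0.28, edgeR adjusted p = 0.00783), a call lost without NC replicate 2 (1.07, edgeR adjusted p = 0.0506). Kit, the stem cell factor receptor, stood at 125 ± 17.1 and 117 ± 15.8 FPKM (-0.15 ± 0.17, edgeR adjusted p = 0.704), and Fcer1a had at most 48 estimated counts in any library.

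The other genes with the largest falls were Aspg, an asparaginase gene (3.08 ± 0.459 FPKM in NC, 0 counts in SH, at least 61.6-fold lower, edgeR adjusted p = 1.04e-07), and Atp6v0d2, a subunit of the vacuolar proton pump (-4.81 ± 0.67, edgeR adjusted p = 8.21e-05). The potassium channel gene Kcnk6 fell by 4.01 ± 0.50 (edgeR adjusted p = 2.5e-05), the RNA export family member Nxf7 by 3.98 ± 0.24 (edgeR adjusted p = 3.14e-09) and the septin gene Sept5 by 3.94 ± 0.40 (edgeR adjusted p = 3.28e-06). Rises were led by Ddc, aromatic amino acid decarboxylase (4.81 ± 1.25, edgeR adjusted p = 0.0172), Efcab12 (4.53 ± 0.85, edgeR adjusted p = 0.00151) and the serpin gene Serpina3g (4.27 ± 0.93; 0.490 to 9.88 ± 6.35 FPKM, edgeR adjusted p = 0.00491). Tex21 (4.03 ± 0.90), Sh2d4a (3.58 ± 0.66), Adgrg5 (3.42 ± 0.62), Eya2 (3.19 ± 0.76), Mmgt2 (3.18 ± 0.57), Krt80 (3.17 ± 0.52) and Hgfac (3.14 ± 0.36) rose as well. For Mmgt2 only NC was low in all its libraries (mean 0.301 FPKM). Means were 2.91 in SH, 2.53 in ICI, 2.38 in Tamo, 2.61 in NC_E2, 2.87 in SH_E2, 1.99 in ICI_E2 and 2.34 in Tamo_E2. ICI_E2 replicate 3, at 0.294 FPKM, was as low as NC. Mmgt2 did not pass in SH_E2 against NC_E2 (0.09, edgeR adjusted p = 0.959). Ddc lost its call without NC replicate 2 or 3 (edgeR adjusted p = 0.0786 and 0.0865) and Eya2 without SH replicate 1 (2.56, edgeR adjusted p = 0.0503).

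Of the gene lists, MAPK feedback and immediate early genes changed most: 17 of 30 fell and 0 rose (19 and 0 adjusted over the list alone; median -0.85, camera adjusted p = 1.08e-21, adjusted p = 0.0116 with an estimated correlation). Jun, an AP-1 subunit, fell from 28.3 ± 4.95 to 5.23 ± 1.65 FPKM (-2.49 ± 0.29, edgeR adjusted p = 1.08e-05). The zinc finger transcription factor genes Egr1 (53.2 ± 14.2 to 8.71 ± 5.23 FPKM; -2.67 ± 0.51, edgeR adjusted p = 0.00185) and Egr3 (-2.86 ± 0.52, edgeR adjusted p = 0.00116) fell too. Klf2 fell by 3.86 ± 0.95 (edgeR adjusted p = 0.0123), a call lost without NC replicate 3 (-3.17, edgeR adjusted p = 0.0584), SH replicate 1 (edgeR adjusted p = 0.0647) or SH replicate 3 (edgeR adjusted p = 0.0646). Of the erythroid and megakaryocyte genes, 2 of 7 rose and 0 fell (4 and 1 over the list alone; camera adjusted p = 0.00085, adjusted p = 0.0158 with an estimated correlation). They were the platelet factor gene Pf4 (6.73 ± 1.10 to 37.7 ± 6.10 FPKM; 2.42 ± 0.24, edgeR adjusted p = 2.4e-06) and the integrin gene Itga2b (1.38 ± 0.14, edgeR adjusted p = 2.82e-06). Among the tested genes of the cell type lists too small for camera, only Lyz2 and Ighm passed. The myeloid lysozyme gene Lyz2 rose from 4.32 to 10.7 FPKM (edgeR adjusted p = 0.00137) and the immunoglobulin heavy chain gene Ighm from 0.134 to 2.47 (edgeR adjusted p = 0.00928). Lck stood at 1.24 FPKM in NC and 0.795 in SH (edgeR adjusted p = 0.297), and Sparc at 0.722 and 0.467 (edgeR adjusted p = 0.678). Pdgfrb, of mesenchymal cells, stood at 10.1 and 17.6 FPKM (edgeR adjusted p = 0.0952), Fcgr1 at 1.76 and 4.56 (edgeR adjusted p = 0.330), the macrophage gene Cd68 at 20.2 and 19.7 (edgeR adjusted p = 0.765) and Nkg7 at 2.83 and 2.44 (edgeR adjusted p = 0.868).

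Antigen presentation and checkpoint genes were shifted up, with 6 of 20 rising and 0 falling (8 and 1 over the list alone; camera adjusted p = 0.00496). The adjusted p = 0.0508 with an estimated correlation, and 0.0175 with that correlation and the replicate block. Tap1, the peptide transporter of class I presentation, rose from 7.91 ± 0.904 to 16 ± 3.14 FPKM (0.95 ± 0.20, edgeR adjusted p = 0.00409). Pdcd1lg2 (0.90 ± 0.26, edgeR adjusted p = 0.0344), H2-Q4 (0.85 ± 0.26, edgeR adjusted p = 0.0440) and the immunoproteasome gene Psmb8 (0.74 ± 0.20, edgeR adjusted p = 0.0202) rose with less stable calls. H2-Q4 lost its call without any 1 of the 6 libraries (edgeR adjusted p up to 0.174, without NC replicate 1). Pdcd1lg2 lost it without NC replicate 2 or 3 or SH replicate 1 (edgeR adjusted p = 0.164, 0.123 and 0.182), and Psmb8 without NC replicate 1 or 2 or SH replicate 3 (edgeR adjusted p = 0.0906, 0.0633 and 0.140).

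Estrogen response genes were shifted down, with 1 of 19 rising and 4 falling (1 and 5 over the list alone; camera adjusted p = 0.00496, adjusted p = 0.285 with an estimated correlation). The falls were Ccnd1, cyclin D1 (121 ± 7.01 to 49.1 ± 7.71 FPKM; -1.35 ± 0.14, edgeR adjusted p = 4.76e-06), Egr3, the survival gene Bcl2 (-0.76 ± 0.17, edgeR adjusted p = 0.00682) and Siah2 (-0.56 ± 0.14, edgeR adjusted p = 0.0112). Siah2 lost its call without NC replicate 2 (-0.51, edgeR adjusted p = 0.0529) or SH replicate 1 (-0.43, edgeR adjusted p = 0.0686). Ccnd1 and Egr3 are also members of the immediate early list, and Greb1 did not pass (-0.27 ± 0.30, edgeR adjusted p = 0.691).

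Other lists, of biosynthesis and stress genes, were shifted down with calls that did not hold with an estimated correlation. Of unfolded protein response genes, 6 of 26 fell and 0 rose (14 and 1 over the list alone; camera adjusted p = 1.45e-05, adjusted p = 0.367 with an estimated correlation), among them the chaperone genes Hsp90b1 (-0.42 ± 0.10) and Pdia4 (-0.42 ± 0.10), Edem1 (-0.62 ± 0.11) and Dnajb9 (-0.93 ± 0.26). Dnajb9 lost its call without NC replicate 1 or 2 or any SH replicate (edgeR adjusted p = 0.0962, 0.121, 0.059, 0.0732 and 0.0929). Of ribosome biogenesis genes, 5 of 34 fell and 0 rose (6 and 0 over the list alone; camera adjusted p = 0.000431, adjusted p = 0.367 with an estimated correlation). They included Rrp12 (-0.66 ± 0.09, edgeR adjusted p = 4.14e-05), Gnl3 (-0.47 ± 0.10, edgeR adjusted p = 0.00465), Nolc1 (-0.71 ± 0.17, edgeR adjusted p = 0.00928) and Rrp9 (-0.66 ± 0.19, edgeR adjusted p = 0.0372). Nolc1 lost its call without NC replicate 3 or SH replicate 1 (edgeR adjusted p = 0.0643 and 0.0576), and Rrp9 without NC replicate 2 or 3 or SH replicate 1 or 2 (edgeR adjusted p = 0.0619, 0.164, 0.153 and 0.106).

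Of the genes for amino acid supply and the integrated stress response, 4 of 32 fell and 1 rose (6 and 1 over the list alone; camera adjusted p = 0.00677, adjusted p = 0.623 with an estimated correlation). The cystine transporter gene Slc7a11 fell by 1.23 ± 0.23 (32.2 ± 7.30 to 14.3 ± 2.56 FPKM, edgeR adjusted p = 0.00167), the glutamine transporter gene Slc38a2 by 0.71 ± 0.15 (edgeR adjusted p = 0.00416) and the serine synthesis gene Psat1 by 0.57 ± 0.11 (edgeR adjusted p = 0.00161). Mthfd2 fell by 0.36 ± 0.08 (edgeR adjusted p = 0.00789), a call lost without NC replicate 3 (-0.31, edgeR adjusted p = 0.0523). Cholesterol synthesis genes were shifted down with 0 of 26 passing (median -0.28, camera adjusted p = 0.0220, adjusted p = 0.904 with an estimated correlation). Hmgcs1 stood at 66.6 ± 2.66 and 49.1 ± 26.9 FPKM (-0.49 ± 0.45); the SH libraries had 18.8, 70.02 and 58.5, so the lower mean rests on replicate 1.

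The remaining lists did not pass in camera. Members that rose and fell were 3 and 4 of 22 mast cell genes, 2 and 1 of 17 cytokines, 3 and 0 of 19 p53 targets, 2 and 6 of 31 lysosome genes, 3 and 2 of 21 NF-kB targets and 1 and 3 of 27 actin and adhesion genes. They were 1 and 0 of 10 receptor and coregulator genes, 1 and 1 of 15 fatty acid synthesis, 1 and 1 of 11 LXR target, 1 and 1 of 15 heat shock, 0 and 2 of 25 NRF2 target, 1 and 2 of 35 hypoxia and glycolysis and 1 and 0 of 37 oxidative phosphorylation genes. Of 37 S phase, 35 mitosis, 15 mitochondrially encoded, 37 ribosomal protein and 7 histone genes, 0 passed. Interferon genes (2 and 0 of 24; median -0.15, mean 0.04, camera direction up) and apoptosis regulators (2 and 1 of 23; median -0.01, mean 0.02, camera direction down) had signs that differ between measures.

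In all, edgeR called 1105 genes for SH against NC, 600 higher and 505 lower, of which 371 changed at least 2-fold. The groups did not overlap for 1097 of them, and for 26.4% of all tested genes against a chance share of 10%. With the replicate block edgeR called 2572 genes (1335 higher, 1237 lower), including 1104 of the 1105, and edgeR on the 6 libraries alone called 557. On the 6 libraries alone the calls of Gzmc (edgeR adjusted p = 0.0580), Slc38a2 (0.0578), Gnl3 (0.0551), Pdia4 (0.0706), Nolc1 (0.0525), Siah2 (0.0940), Mthfd2 (0.101), Dnajb9 (0.0735), Pdcd1lg2 (0.124), Psmb8 (0.0666) and Rrp9 (0.0891) were lost. On replicates 2 and 3 alone those of Hsp90b1 (edgeR adjusted p = 0.0724), Slc38a2 (0.0942), Gnl3 (0.0844), Pdia4 (0.0673), Siah2 (0.0919), Mthfd2 (0.0507), Eya2 (0.110), Dnajb9 (0.238), Psmb8 (0.141) and Rrp9 (0.183) were lost. Without a filter H2-Q4, Pdcd1lg2, Psmb8 and Rrp9 were lost (edgeR adjusted p = 0.0896, 0.0729, 0.0513 and 0.0914), without chromosome 19 genes H2-Q4 (0.0516), and in limma Dnajb9 (0.0623 and 0.0602). Both arms carry a vector, but no second hairpin or untransfected group is labelled, so the hairpin and other differences between the cell populations cannot be told apart.

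**Figure D3:**
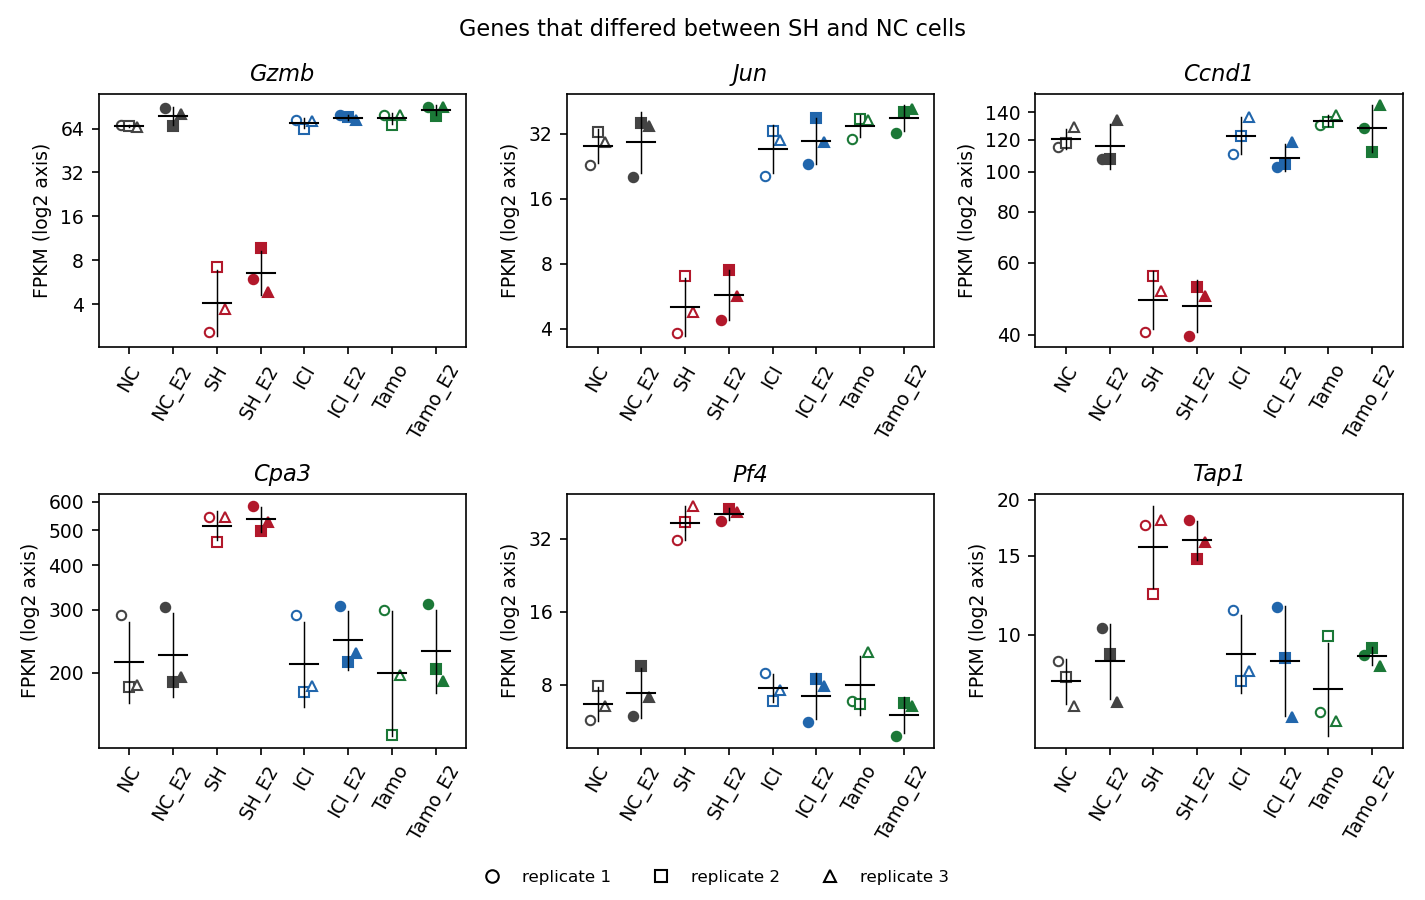
FPKM (log2 axis) of Gzmb, Jun, Ccnd1, Cpa3, Pf4 and Tap1 in the 8 groups; each point is a library (shape gives the replicate number, open without and filled with E2), and lines give the geometric mean ± 1 SD, n = 3. Both SH groups stand apart from the other 6 for Gzmb (66.2 FPKM in NC, 4.48 in SH, arithmetic means), Jun, Ccnd1, Cpa3 and Pf4. They do so narrowly for Tap1 (at least 12.34 FPKM, against at most 11.51).

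Whether the SH difference is also present with E2 was examined in other libraries, a contrast added after the data were seen. Serpina3g (4.70), Efcab12 (4.32) and Sh2d4a (4.0) rose in SH_E2 against NC_E2, and Tex21 was at least 33.1-fold higher. Aspg (at least 64.1-fold), Atp6v0d2 (at least 21.8-fold) and Gzmc (at least 10.1-fold) were lower, with Mrgprb1 at -5.56 and the serpin gene Serpinb7 at -4.60. Ddc rose by 4.15, a call lost without any 1 of the 6 libraries (edgeR adjusted p = 0.0512 to 0.114) and without a filter (edgeR adjusted p = 0.0645). Jun (-2.41, edgeR adjusted p = 1.55e-05), Egr1 (-2.52) and Klf2 (-4.57) fell, and Pf4 (2.38, edgeR adjusted p = 2.85e-06), Itga2b (1.35) and the galectin gene Lgals9 (0.84, edgeR adjusted p = 0.000128) rose. Cpa3 rose by 1.18 ± 0.28 (edgeR adjusted p = 0.00848), a call lost without NC_E2 replicate 2 (1.05, edgeR adjusted p = 0.0528), and Tap1 by 0.83, lost without NC_E2 replicate 3 (0.70, edgeR adjusted p = 0.0715).

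In SH_E2 against NC_E2 edgeR called 1168 genes, 646 higher and 522 lower, and 778 without NC_E2 replicate 3; edgeR on the 6 libraries alone called 554. Across the 12183 genes the SH effects without and with E2 correlated at r = 0.614 (Spearman 0.724; -0.0769 to 0.0850 in simulations; no library shared), and lower values came without NC_E2 replicate 3 (0.538). Of the genes called in both, 480 rose in both (31.8 expected by chance), 384 fell in both (21.6 expected) and 0 moved oppositely. Over the 1105 genes called without E2, the slope of the change with E2 was 0.856 (95% interval 0.784 to 0.938, from resampling genes and not libraries). The lists called were immediate early genes (0 rose and 17 of 30 fell; camera adjusted p = 3.59e-23, adjusted p = 0.00856 with an estimated correlation), erythroid and megakaryocyte genes (3 rose; camera adjusted p = 0.00049, adjusted p = 0.0118 with an estimated correlation) and antigen presentation genes (4 rose; camera adjusted p = 0.00254, adjusted p = 0.0348 with an estimated correlation). Unfolded protein response (7 fell; camera adjusted p = 6.41e-05) and ribosome biogenesis genes (5 fell; camera adjusted p = 9.94e-05) both had an adjusted p = 0.440 with an estimated correlation, and amino acid stress genes (1 rose, 5 fell; camera adjusted p = 0.00254) an adjusted p = 0.513.

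**Figure D4:**
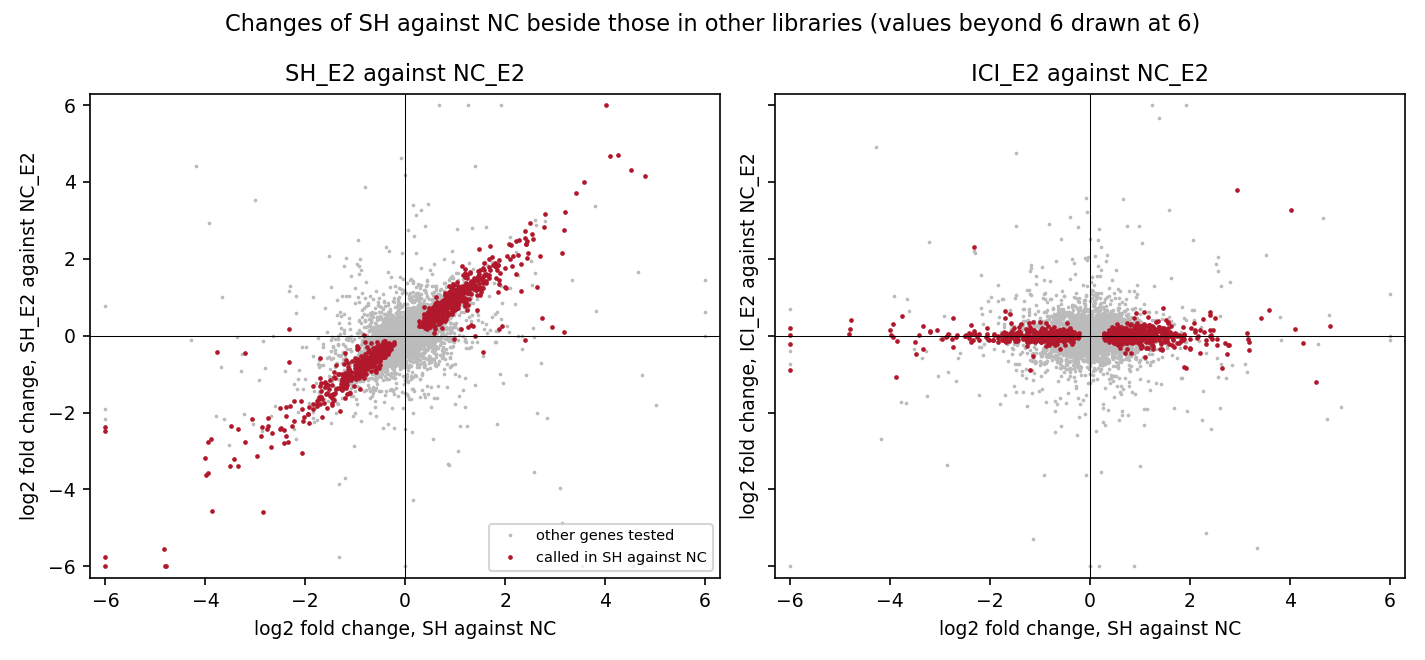
Log2 fold change of each tested gene in SH against NC (horizontal) beside SH_E2 against NC_E2 (left) and ICI_E2 against NC_E2 (right), in libraries not shared; red points are the 1105 genes called in SH against NC, grey the others, and values beyond 6 are drawn at 6. The slope over red points is 0.856 on the left and 0.0122 on the right.

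The SH difference had a chromosomal component, looked for after the data were seen. Of 450 tested genes on chromosome 19, 78.7% were lower in SH than in NC, with a median of -0.32 on the log2 scale, while medians of the other chromosomes ran from -0.05 to 0.13. Chromosomes 3 and 1 were shifted the other way, with medians of 0.13 and 0.10 in SH against NC and 0.12 and 0.09 in SH_E2 against NC_E2. Of their called genes in SH against NC, 85 of 105 and 48 of 68 were higher. On chromosome 19, all 7 windows of 10 Mb had a median below 0 (-0.48 to -0.14). With E2 the chromosome 19 median was -0.35 and 80.4% of its genes were lower. Without E2, its median lay below that of all 100000 random gene sets of the same size (permutation p = 1e-05, the smallest reachable), though genes are not independent. Between libraries, the chromosome 19 score was at most -0.31 in the 6 SH libraries and at least -0.04 in the others (chromosome 3: at least 0.11 and at most 0.03; chromosome 1: at least 0.05 and at most 0.03). Its difference was -0.32 over both conditions (stratified exact permutation p = 0.005, the smallest reachable). Chromosome 19 held 97 of the 1105 called genes, 86 lower and 11 higher, among them Rrp12, Nolc1 and Psat1, which fell, and Pdcd1lg2, which rose.

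**Figure D5:**
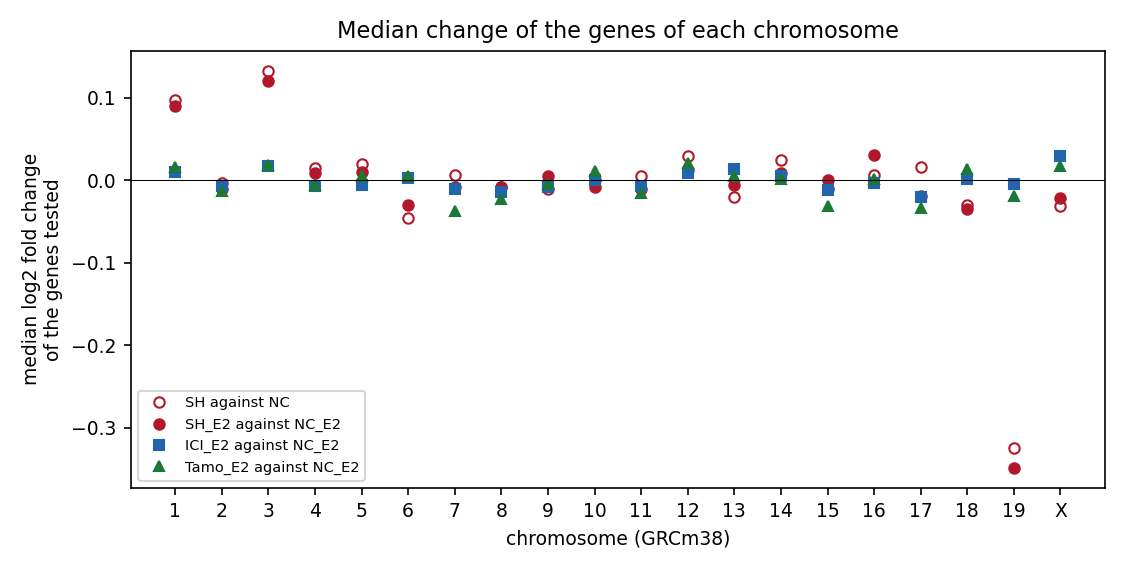
Median log2 fold change (vertical) of the tested genes of each chromosome (horizontal, GRCm38) in SH against NC (open red circles), SH_E2 against NC_E2 (filled red circles), ICI_E2 against NC_E2 (blue squares) and Tamo_E2 against NC_E2 (green triangles). Chromosome 19 stands at -0.32 and -0.35 in the SH contrasts and near 0 in the inhibitor contrasts.

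Finally, cells with either antiestrogen were compared with vector controls. Ccdc71 was the only gene to pass in each case: it stood at 3.83 ± 0.510 FPKM in NC, 10.2 ± 0.407 in ICI (1.41 ± 0.19, edgeR adjusted p = 0.00668) and 11 ± 0.190 in Tamo (1.53 ± 0.19, edgeR adjusted p = 0.00205). Its level was 9.97 ± 1.10 in SH, so that NC was the lowest of the 8 groups. The call in ICI was lost without ICI replicate 2 (1.38, edgeR adjusted p = 0.0525) or NC replicate 3 (1.32, edgeR adjusted p = 0.131) and on the 6 libraries alone (edgeR adjusted p = 0.237), and that in Tamo on the 6 libraries alone (edgeR adjusted p = 0.0628). Both were lost on replicates 2 and 3 alone (edgeR adjusted p = 0.807 in ICI and 0.160 in Tamo). edgeR called 1 gene with ICI (119 at an unadjusted p under 0.05) and 1 with Tamo (430), and the same numbers with the replicate block (237 and 1068 at an unadjusted p under 0.05); DESeq2 called 5 and 11, and limma 1 and 1. Without ICI replicate 3 or NC replicate 2, 2 genes passed for ICI; for Tamo 2 passed without NC replicate 2, and 3 without Tamo replicate 1 or 3. Of the lists, 0 passed with ICI. Immediate early genes were shifted up with Tamo (median 0.18, 0 members passing, camera adjusted p = 0.0370, adjusted p = 0.990 with an estimated correlation), and that was the only list without the replicate block. With the block, 7 lists passed in Tamo: immediate early, cytokine, NF-kB, interferon and lysosome genes shifted up, and mitosis and mitochondrially encoded genes down, each lost with an estimated correlation (lowest adjusted p = 0.0725).

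ICI-182780, a steroidal antiestrogen, and tamoxifen, a triphenylethylene, differed at no gene that passed. The smallest p belonged to Esco1 (0.57 ± 0.10 higher with ICI, edgeR adjusted p = 0.215), Arfip2 (0.71 ± 0.14, edgeR adjusted p = 0.347), Caap1 (0.52), Syncrip (0.57) and Dnajc14 (1.18). edgeR called 0 genes (392 at an unadjusted p under 0.05), 0 with the replicate block (986 at an unadjusted p under 0.05), limma 0 and DESeq2 7; without ICI replicate 3 or Tamo replicate 3, 1 passed. The 95% interval of the difference lay within 2-fold for 79.4% of genes and within 1.5-fold for 50.6%, so smaller differences remain possible for many genes. Camera called 0 lists without the replicate block and 6 with it (mitosis and mitochondrially encoded genes higher with ICI; cytokine, lysosome, immediate early and NF-kB genes lower), all lost with an estimated correlation (lowest adjusted p = 0.0865). Doses are not labelled and may not match. The effects of both drugs against NC correlated at r = 0.489 across genes, the value that shared NC libraries alone gave in simulations (0.490, from 0.382 to 0.548). The covariance was 0.0740 against 0.0732, while the Spearman value of 0.362 was below its simulated mean of 0.455. With E2 present the drug effects against NC_E2 correlated at 0.513 (0.451 to 0.538 in simulations), and their covariance of 0.0878 lay above the simulated range (0.0593 to 0.0799). Their Spearman value was 0.373 (simulated mean 0.454). The simulations hold no correlation between genes beyond the replicate number, so the higher covariance does not by itself show a shared effect. With no library shared, ICI against NC and Tamo_E2 against NC_E2 correlated at -0.0962 (-0.135 to 0.0862 in simulations), and Tamo against NC and ICI_E2 against NC_E2 at -0.0639 (-0.0860 to 0.119).

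With E2 present, contrasts added after the data were seen, neither drug had a gene that passed. The smallest p belonged to Eif1a (-1.36), Sacm1l (0.64), Akap12 (0.59), Cadm4 (0.70) and Cldnd1 (0.97) for ICI_E2 against NC_E2. For Tamo_E2 against NC_E2 they were Sema3d (0.40), Pagr1a (-1.82), Sec22c (-1.06), Akap12 (0.57) and Sat1 (0.79). edgeR called 0 genes for each (175 and 301 at an unadjusted p under 0.05), and 0 for Tamo_E2 with the replicate block (789 at an unadjusted p under 0.05), limma 0 and 0, DESeq2 5 and 2, and edgeR on the 6 libraries alone 3 and 2. Eif1a passed for ICI_E2 on the 6 libraries alone (edgeR adjusted p = 0.0198) and in DESeq2 (adjusted p = 0.0452). NC replicate 1 and SH_E2 replicate 3 were as low for this gene as the ICI_E2 libraries. Mitochondrially encoded genes were shifted up in ICI_E2 (camera adjusted p = 2e-08, adjusted p = 0.359 with an estimated correlation), where their share was 5.52 ± 0.435% against 4.98 ± 0.206% in NC_E2. In Tamo_E2 mitochondrially encoded genes (median 0.17, camera adjusted p = 0.000111) and immediate early genes (0.13, camera adjusted p = 0.0173) were shifted up, and ribosomal protein genes (-0.12, camera adjusted p = 1.32e-05) and oxidative phosphorylation genes (-0.10, camera adjusted p = 0.000367) down. All 4 had an adjusted p = 0.888 with an estimated correlation, and 0 of their members passed. With the replicate block 11 lists passed in Tamo_E2: in addition cytokine, interferon, NF-kB, lysosome and estrogen response genes shifted up, and S phase and ribosome biogenesis genes down, each lost with an estimated correlation (lowest adjusted p = 0.211). Over the 1105 genes called for SH against NC, the slope was 0.0122 for ICI_E2 (95% interval -0.00883 to 0.0359) and -0.0334 for Tamo_E2 (-0.0541 to -0.0134). The intervals resample genes and not libraries, so they do not measure the spread between libraries. The negative slope for Tamo_E2 therefore does not by itself show an effect. Effects of the same drug without and with E2 correlated across genes at -0.0447 for ICI (-0.0637 to 0.120 in simulations) and at -0.124 for Tamo (-0.103 to 0.105).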

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

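The prediction on chromosome copies was written after the result was seen, and those on sequence composition and on the inhibitors before their tests were run. The lower level of chromosome 19 genes in SH cells is a signal that none of the planned comparisons used: the median log2 fold change was -0.32 in SH against NC and -0.35 in SH_E2 against NC_E2, in libraries not shared. Fewer copies of chromosome 19 in the SH population remain a candidate explanation, since 78.7% of its genes were lower and every window of 10 Mb lay below 0. GC content, gene length and expression level were excluded, as the median after regression on them was -0.33 with the replicate block. Its 95% bootstrap interval, from resampling chromosome 19 genes and not libraries, was -0.36 to -0.29, and 12169 genes had these measures. For acute loss of estrogen receptor signalling, the median in ICI_E2 against NC_E2 was -0.0048, so chromosome 19 genes were not lower with ICI-182780. However, E2 in NC and ICI_E2 against NC_E2 each called 0 genes, so nothing here shows that the drug blocked receptor signalling. That median therefore cannot decide on acute loss of signalling, which stays open. Copy number itself was not analysed here, and whether the cells differed before the hairpin was introduced cannot be told from these libraries.

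The E2 effect on several gene lists differed between arms by camera on the difference of effects. Mitochondrially encoded genes had a median difference from NC of 0.15 in SH (camera adjusted p = 0.00397), 0.19 in ICI (camera adjusted p = 2.52e-05) and 0.27 in Tamo (camera adjusted p = 7.8e-05); with an estimated correlation the adjusted p = 0.995, 0.984 and 0.995. These differences share the NC and NC_E2 libraries, in which these genes took 5.34 ± 0.134% and 4.98 ± 0.206% of the library. They are therefore not independent results. In Tamo, oxidative phosphorylation genes had a median difference of -0.17 (camera adjusted p = 0.000829) and ribosomal protein genes of -0.18 (camera adjusted p = 7.8e-05), both with an adjusted p = 0.995 with an estimated correlation.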

How the results depend on the processing

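No call changed direction. Of the 86 calls of named genes, 47 were kept under every alternative and 39 were lost under at least 1 (225 of 1565 values); of 123 values that did not pass, 38 alternatives brought one past the threshold. The replicate block changed no call of a named gene or list, and moved no count of genes that passed by over 1.5 times, beyond those given in the text and here. For ICI_E2 against NC_E2 it called 0 genes, with 334 at an unadjusted p under 0.05 against 175. In SH_E2 against NC_E2 it gave 7 lists against 6, with cholesterol synthesis genes shifted down (camera adjusted p = 0.0244, adjusted p = 0.846 with an estimated correlation). Between SH_E2 and NC_E2, and between ICI_E2 and NC_E2, 2 of the 3 same-numbered pairs were over 0.1. The lowest pair fell just short in each (0.0967 and 0.0949), so the check did not settle whether the numbers pair these libraries. Causes were not tested except where fewer genes or libraries are the alternative itself. Depth leaves only bounds for genes near the floor.

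Counts of genes for E2 in NC were 3 on the groups of the contrast alone, 4 in DESeq2, 1 on replicates 2 and 3, and 0 to 1 without 1 library. For E2 in SH they were 1 without a filter, 3 on its groups alone, 2 in DESeq2, 1 on replicates 2 and 3, and 0 to 1 without 1 library. For E2 in ICI they were 3 on its groups alone, 1 with the replicate block, 10 in DESeq2, and 0 to 1 without 1 library. For E2 in Tamo they were 3 with the replicate block, 6 in DESeq2, 4 on replicates 2 and 3, and 0 to 1 without 1 library. SH against NC gave 557 genes on its groups alone, 2572 with the replicate block, and 781 to 910 without 1 library; the other alternatives gave 739 (mean FPKM 5) to 1453 (DESeq2), with 961 without chromosome 19 genes. SH_E2 against NC_E2 gave 741 at mean FPKM 5, 554 on its groups alone, 2667 with the replicate block, 747 on replicates 2 and 3, and 778 to 898 without 1 library. ICI against NC gave 0 on its groups alone, 5 in DESeq2 and 0 to 2 without 1 library. Tamo against NC gave 0 on its groups alone, 11 in DESeq2, 5 on replicates 2 and 3, and 1 to 3 without 1 library. ICI against Tamo gave 7 in DESeq2, 3 on replicates 2 and 3, and 0 to 1 without 1 library. ICI_E2 against NC_E2 gave 3 on its groups alone and 5 in DESeq2, and Tamo_E2 against NC_E2 2 and 2.

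For the difference of the E2 effect from that in NC, SH gave 1 in DESeq2, 1 on replicates 2 and 3 and 0 to 1 without 1 library; ICI gave 4 in DESeq2 and 0 to 1 without 1 library. Tamo gave 1 on its groups alone, 16 in DESeq2, 2 on replicates 2 and 3, and 0 to 1 without 1 library. E2 over the 4 arms gave 4 without a filter, 1 at mean FPKM 5, 14 with the replicate block, 12 in DESeq2, 2 and 2 in limma, 3 on counts divided by 4, 0 on replicates 2 and 3, and 2 to 8 without 1 library. Epb41l4b lost its call there in 26 of 34 alternatives, Por in 27 of 35 and Rmnd5b in 23 of 35, leave-one-out fits included, whereas Nlrp3 and Galnt10 lost theirs only on replicates 2 and 3 (2.33 and 0.38, edgeR adjusted p = 0.285 and 0.343), with fewer libraries.

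Of the gene list tests over all planned contrasts 21 passed, 2 with an estimated correlation, 10 by fry, 33 with the replicate block and 3 with an estimated correlation and the replicate block. The Esr1 difference over both conditions ran from -0.63 (without NC replicate 3, exact permutation p = 0.02) to -0.33 (without NC replicate 2) when 1 library was left out. The correlation of E2 effects in NC and SH was 0.644 at mean FPKM 5, and that of inhibitor effects -0.0962 with no shared library. The correlation of SH effects without and with E2 was 0.782 at mean FPKM 5, 0.759 and 0.689 in limma with pseudocounts 1 and 0.1, and 0.538 to 0.590 without 1 library (lowest without NC_E2 replicate 3; 0.544 without NC replicate 3 and 0.553 without SH replicate 1).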

Other observations

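All genes of this paragraph were chosen after their values were seen. The mast cell list did not pass in SH cells, and the single genes here are no test of it. The tryptase genes Tpsb2 (-3.34 without E2, edgeR adjusted p = 0.0035; -3.40 with E2, edgeR adjusted p = 0.00355) and Tpsab1 (-2.77, edgeR adjusted p = 0.000724; -2.43, edgeR adjusted p = 0.00198) fell. The mast cell protease genes Mcpt2 (2.0, edgeR adjusted p = 0.000134; 1.26, edgeR adjusted p = 0.00678) and Mcpt8 (1.67, edgeR adjusted p = 0.00654; 1.79, edgeR adjusted p = 0.00407) rose. The transcription factor genes Gata1 (0.18), Gata2 (-0.11) and Mitf (0.23) and the histamine synthesis gene Hdc (0.12) did not pass without E2. Of the ERK feedback genes, Dusp6 (-1.06, edgeR adjusted p = 0.0157), Etv4 (-0.71, edgeR adjusted p = 0.00314) and Spred1 (-0.55, edgeR adjusted p = 0.00907) fell, while Fos (0.08, edgeR adjusted p = 0.970) and Myc (-0.18, edgeR adjusted p = 0.593) did not pass. With E2, Lyz2 (1.59, edgeR adjusted p = 0.000152) and Ighm (4.67, edgeR adjusted p = 0.00478) rose as they did without it.

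Over all 24 libraries, the highest mean levels of other cell type markers were 2.96 FPKM for Nkg7 among T and NK cell genes, 0.745 for Ighm among B cell genes, 20.3 for Cd68 among macrophage and neutrophil genes, 11.7 for Pdgfrb among fibroblast and endothelial genes, 0.614 for Cldn7 among epithelial genes and 101 for Tfrc among erythroid and megakaryocyte genes. In SH and SH_E2 the means were 2.47 and 2.73 for Ighm, 17.6 and 17.0 for Pdgfrb and 125 and 126 for Tfrc.

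For the following patterns, the tests of the ICI_E2 slope, of the ratio of E2 effects in ICI and of the replicate numbers were chosen after the result was seen. The gene changes of SH against NC could come from acute loss of receptor signalling, from direct dosage of chromosome 19 genes or from the assignment of libraries to groups by chance. For the first, the slope of the change in ICI_E2 against NC_E2 over the 1105 genes was 0.0122. With E2 present, these genes thus did not move with ICI-182780 as they did in SH. However, E2 in NC and ICI_E2 against NC_E2 each called 0 genes, so nothing here shows that the drug blocked receptor signalling. The slope therefore cannot decide on the first, which stays open. Direct dosage of chromosome 19 can act only on its own genes, which made up 8.78% of the 1105, against 3.69% of tested genes. Only 450 genes of chromosome 19 were tested, so they could not have made up most of the 1105, and the share is no test of dosage. Dosage of other chromosomes, and effects of dosage on genes elsewhere, were not tested. Of 100 regroupings of the 12 libraries within E2 conditions, 1, the real one, called as many genes over both conditions (2517 genes for the real groups, at most 562 for any other). Selection or clonal differences between the populations, RNA from other cells and effects of the hairpin on other targets were not tested, and remain possible.

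The genes that rose with E2 over the 4 arms could reflect a receptor effect that ICI-182780 blocks, the assignment of libraries by chance or differences between replicate numbers. The mean E2 effect of the 6 rising genes in ICI was 1.53 times that in NC, but they were called on all 4 arms, ICI included, which selects against a blocked effect, so the first stays open. Of 100 swaps of the E2 labels within same-numbered pairs, 1 called as many as 7 genes, the real labels themselves (at most 1 for any other). The swaps do not repeat the choice of this contrast, which was made after the data were seen, so chance assignment is not excluded. All 7 genes passed with the replicate number as a block, but each number occurs equally with and without E2, so this decides nothing on replicate numbers. An effect of the E2 solvent could not be tested, since no vehicle group is labelled.

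Of the 12 genes that rose in the blocked fit over the 4 arms, 4 (the neighbours Rmnd5b and N4bp3, and Galnt10 and Nlrp3) lie on chromosome 11 between 51623671 and 59566956 (GRCm38), an observation made after the positions were seen. Chromosome 11 holds 1022 of the 12183 genes tested (8.39%; one-sided exact hypergeometric test p = 0.0141, for a chromosome chosen after the positions were seen and not adjusted for the others). Tap2, the partner of Tap1, also rose in the blocked fit (0.38, edgeR adjusted p = 0.00093).

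Regroupings of the libraries were also counted for each contrast of 2 groups, where 10 splits are too few for a share under 0.05. As many genes as with the real groups were called in 1 of 10 splits for SH against NC (real 1105, highest other 0), SH_E2 against NC_E2 (1168, 2) and Tamo against NC (1, 0), and in 3 of 10 for ICI against NC (1, 1). A real count of 0 is reached by any split, so the following say nothing about chance: 10 of 10 for E2 in NC (highest other 0), SH (2), ICI (0) and Tamo (1), for ICI against Tamo (2) and for ICI_E2 (2) and Tamo_E2 (1) against NC_E2. The same holds for 100 of 100 for the difference of the E2 effect from that in NC in SH (highest other 581, in splits that mix SH and NC libraries), ICI (1) and Tamo (3).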
